A study of Homo sapiens with 60 samples.

How the data were processed

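Messenger RNA of 60 untreated human cancer cell lines, the panel of lines known as the NCI-60, was measured on Affymetrix GeneChip arrays, 1 array per line. The sample titles carry a panel code before the name of each line. From knowledge of the field the codes stand for leukemia (LE, 6 lines), breast (BR, 7), central nervous system (CNS, 6), colon (CO, 7), renal (RE, 8), non-small cell lung (LC, 9), ovarian (OV, 6), prostate (PR, 2) and melanoma (ME, 8). The line NCI/ADR-RES has a code that names no panel, and it entered no comparison. Lines are named as in the titles, except that 1 colon line and 2 renal lines are given by panel and replicate number. Every array is labelled as a different cell line, so by the labels the spread within a panel is the spread between lines. The measurement error of a single line could not be estimated, and the number of arrays limits the precision.

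The deposited table holds 22283 probe sets per array, already summarised by the authors to 1 value per probe set. The values deposited by the authors were read as log2 signal because they run from 2.72 to 13.9. The base of the logarithm, the summarising algorithm and the normalization are not given in the sources used here, so every fold given is conditional on base 2. The medians of the arrays lay between 5.83 and 5.99, a span of 0.157. A rule fixed before the data were examined kept the deposited values as the main setting when this span was under 0.5, with quantile normalization as an alternative.

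Probe sets were named through the platform annotation. Of them, 19071 carried 1 gene symbol, 1043 several and 2169 none. Only those with 1 symbol were used, and 19059 of these matched a RefSeq gene by Entrez identifier. This left 11963 genes, of which 4310 had more than 1 probe set. Each gene was represented by the probe set with the highest mean over the 59 lines with a panel code, a rule that can pick a bright probe set that responds little to the gene. Some listed genes are not reported here. No genome build was named in the sources used here, so no coordinates are given.

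Each panel was compared with the unweighted mean of the other 8 panel means in limma 3.58.1 under R 4.3.3, with lmFit over all 59 lines and eBayes. All 9 comparisons share their lines, so they are not independent of each other. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes within a comparison, and calls of at least 2-fold were also counted. The moderated F test of limma asked whether a gene differed among panels at all. No filter on dim genes was used. Adjusted p-values of single genes come from these limma models.

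The lists of genes, 26 in all, were fixed before the data were examined. Each was tested in each comparison with camera from limma, at a preset correlation between genes of 0.01, with adjustment over the 234 tests of all lists and panels. With an estimated correlation in place of the preset one, 8 of these tests passed instead of 68. Counts of members are over the measured ones. The score of a list in a line is the mean over its members of the log2 value minus the mean of the 9 panel means.

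The genes named for a panel followed a rule fixed before the data were examined. It took, among called genes whose higher side lay above 5.90, the median of all values, the 10 with the largest positive and the 5 with the largest negative difference. From each list tied to the panel it took the first member measured here, whatever its result, and the 4 called members with the largest difference. From a list of drug transporters and drug targets it took the 8 genes with the largest F. Giving these in each panel where they were called was chosen after the data were seen. Genes named outside this rule were chosen after their values were seen, and the text says so. Probe sets of the MAGEA and HLA genes may cross-hybridise between near-identical copies.

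The resemblance of lines was measured by Pearson correlation over the 2000 genes of largest variance, and the count of lines whose nearest line shares their panel was tested with 100000 permutations of the panel codes. The fits were tested on simulated data for 11963 genes with known changes in 50 genes per size. For the leukemia comparison, 48% of genes changed by 0.5 on the log2 scale and 82% of those changed by 1 were called. For the prostate comparison these shares were 18% and 54%, and for the lung comparison 66% and 94%. The simulated noise was normal, independent between genes and equally wide in all panels. Changes of 2 and 4 were planted in the same data, which eases the adjusted threshold. The shares therefore do not give the probability of a call in the real comparisons.

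The alternatives were quantile normalization, centring each array on its median, a filter on dim genes, the mean of all probe sets or the most variable probe set of a gene, all other lines pooled as the reference, eBayes with trend and robust settings, leaving out MDA-MB-435 and MDA-N, averaging MDA-MB-435 with MDA-N and SNB-19 with U251 (pairs catalogued as related), and leaving out each line in turn. A covariate for the 3′ to 5′ difference of the control probe sets, a fit without NCI-H23 and OVCAR-8, and leaving out each line in the list tests were added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.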

Results

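Baseline messenger RNA of 59 cultured human cancer lines in 9 panels was compared to find which genes set each panel apart from the others. The lines are those of a drug screening collection and were profiled without treatment. The array medians differed by no more than 0.157 on the log2 scale. A gene whose values lie below 5.90, the median of all values, can be unexpressed. Among 11963 genes, 3708 differed among the panels by the moderated F test. The number of genes called in a panel ran from 1943 in leukemia to 2 in lung. Among calls of at least 2-fold, 218 were higher and 51 lower in the central nervous system, 155 and 130 in colon, 124 and 8 in renal, 274 and 88 in melanoma, 24 and 0 in ovarian, 11 and 4 in breast and 10 and 0 in prostate lines.

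**Figure D1:**
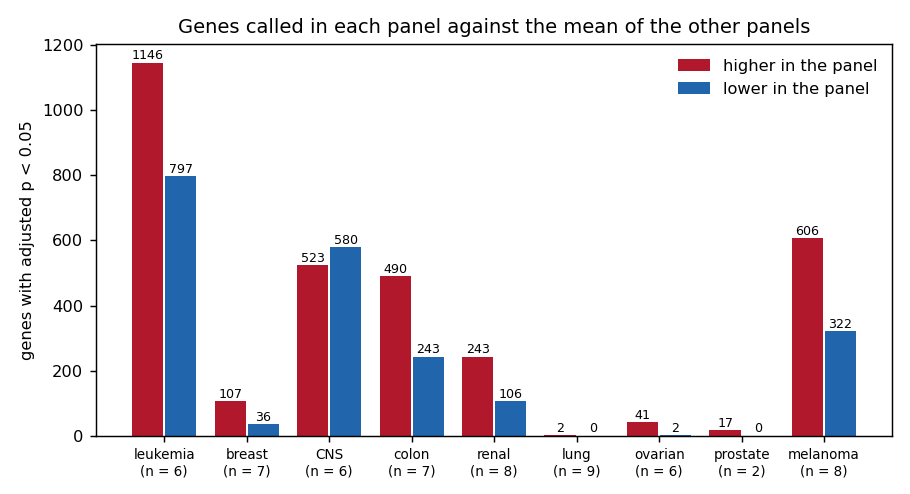
Genes called at an adjusted p under 0.05 in each panel against the mean of the other 8 panel means, with red bars for genes higher and blue bars for genes lower in the panel, and n the number of cell lines. The leukemia panel had 1146 genes higher and 797 lower, and the lung panel had 2 and 0.

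Genes of white blood cells were higher in the leukemia lines, and most measured focal adhesion genes were lower. All 24 measured genes of the leukocyte list were higher, among them MYB, a transcription factor of blood progenitors, CORO1A and HCLS1, regulators of actin in blood cells, and PTPRC, the pan-leukocyte surface protein CD45. MYB averaged 9.72 ± 1.13 (SD, n = 6) against 5.53 in the other panels, a difference of 4.19 ± 0.33 (SE), or 18.2-fold, with an adjusted p of 3.2e-14 and all 6 lines above the median of the other lines. HCLS1 was higher by 3.58 ± 0.16 (SE, adjusted p = 2.74e-24), CORO1A by 3.71 ± 0.33 (SE, adjusted p = 9.87e-13), ARHGDIB by 3.99 ± 0.64 (SE, adjusted p = 5.82e-06) and PTPRC by 2.46 ± 0.21 (SE, adjusted p = 3.55e-13). Outside the list GMFG was higher by 3.34 ± 0.32, DOCK2 by 3.28 ± 0.30 and ITM2A by 2.57 ± 0.44 (SE). The leukocyte list passed camera with the preset (adjusted p = 3.49e-45) and with an estimated correlation (adjusted p = 4.96e-08).

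Most measured genes of attachment to a substrate were lower in the leukemia lines. Of 23 measured focal adhesion genes, 18 were lower and none was higher (camera adjusted p = 3.84e-19, and adjusted p = 0.000204 with an estimated correlation). The caveolae protein CAV1 fell by 3.55 ± 0.74 (SE), the laminin chain LAMC1 fell by 3.10 ± 0.37, the actin cross-linker ACTN1 fell by 2.80 ± 0.32 and the kinase PTK2 fell by 2.69 ± 0.31. The largest difference was that of PLS3, an actin-bundling protein of solid tissues, at 4.53 ± 1.83 (SD, n = 6) against 9.49, or 31.1-fold lower (adjusted p = 6.21e-14). MYOF was 17.5-fold, LGALS3 16-fold, PHLDA1 15.6-fold and CD24 15.3-fold lower. The first member of the list, the integrin ITGA2, differed by -0.49 ± 0.17 (SE), a call lost when any line but RPMI-8226 was left out or when the other lines were pooled. Without NCI-H23 and OVCAR-8, 14 of 35 mesenchymal and matrix genes and 6 of 29 epithelial genes were lower too. So were 8 of 25 targets of the oxidative stress factor NRF2. These lists passed camera with the preset (adjusted p = 2.98e-09, 8.67e-06 and 2.75e-05) but not with an estimated correlation (adjusted p = 0.459, 0.664 and 0.593). With only HL-60(TB) left out, 11, 3 and 4 of their members were lower, and with only RPMI-8226 left out 14, 7 and 8.

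Within the leukemia panel, genes of single blood lineages were carried by different lines. Of 19 T lymphoid genes 17 were higher (camera adjusted p = 3.28e-12, and adjusted p = 0.299 with an estimated correlation), with CD3D, a chain of the T cell receptor complex, higher by 3.18 ± 0.38 (SE). That count fell to 10 without MOLT-4, and CD3E, higher by 1.01 ± 0.24, lost its call there. LEF1, higher by 1.90 ± 0.65, lost its call without CCRF-CEM, MOLT-4 or K-562 and with the other lines pooled. Of 15 myeloid genes 6 were higher (camera adjusted p = 0.00777, and adjusted p = 0.771 with an estimated correlation), and without HL-60(TB) 2 were, with an adjusted p of 0.896. MPO, the granule enzyme myeloperoxidase, reached 12.16 in HL-60(TB) and at most 4.82 in the other leukemia lines. Of 12 erythroid genes 6 were higher (camera adjusted p = 0.000803, and adjusted p = 0.574 with an estimated correlation), and without K-562 3 were, with an adjusted p of 0.181. The embryonic globin HBZ reached 11.04 in K-562 and at most 5.18 elsewhere in the panel. Of 14 B lymphoid and plasma cell genes 8 were higher (camera adjusted p = 0.00045, and adjusted p = 0.449 with an estimated correlation). Without RPMI-8226 3 were, and the antibody joining chain JCHAIN, at 10.3 in that line, was at most 3.25 in the others. CD79A, the first member measured of that list, differed by 0.24 ± 0.14 (SE, adjusted p = 0.262). Of 9 genes of MHC class II presentation only the protease CTSS was higher, by 1.07 ± 0.25 (SE), and the list did not pass (camera adjusted p = 0.671). CD74 there differed by 0.77 ± 0.69 (SE, adjusted p = 0.508).

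In all, 1943 genes were called in the leukemia panel, 1146 higher and 797 lower. Calls of at least 2-fold numbered 184 higher and 410 lower.

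Few genes were called in the breast-coded lines, and markers of luminal breast cells were high in 2 of the 7 lines. The luminal transcription factor GATA3 was higher by 1.94 ± 0.51 (SE, adjusted p = 0.0389) and TRPS1 by 1.69 ± 0.45 (SE, adjusted p = 0.0403). They were the 2 of 24 luminal genes called, while 7 passed when adjusted over the list alone. The list passed camera with the preset (adjusted p = 2.71e-05) but had an adjusted p of 0.521 with an estimated correlation. Without NCI-H23 and OVCAR-8, 2 luminal genes were higher in the breast and 4 in the colon lines, where the list did not pass (camera adjusted p = 0.23). MCF7 and T-47D had luminal list scores of 1.71 and 2.75, and the other 5 lines lay between -0.45 and -0.13. Without T-47D the list had an adjusted p of 0.28 and no member was called, without MCF7 none was called either (list adjusted p = 0.0135), and without HS 578T 1 was. GATA3 lost its call without MCF7 or T-47D. TRPS1 lost its call without MCF7, HS 578T, T-47D or BT-549 and with the 3′ to 5′ covariate. The estrogen receptor gene ESR1 differed by 0.02 ± 0.10 (SE) through its brightest probe set, and by 1.19 through its most variable one, where it was called.

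The breast-coded lines MDA-MB-435 and MDA-N carried melanocyte genes. Their melanocyte list scores were 2.02 and 2.06, against -0.58 to -0.17 in the other 5 breast-coded lines. Over the whole panel no melanocyte gene was called, and the list had a camera adjusted p of 0.0749. It passed, in the higher direction, without MCF7 (adjusted p = 0.00887), MDA-MB-231/ATCC (0.00824), HS 578T (0.00983), T-47D (0.024) or BT-549 (0.0179). MITF, its first member, differed by 0.31 ± 0.42 (SE). Without both lines the melanocyte list was lower in the breast panel (adjusted p = 0.00192, and adjusted p = 0.692 with an estimated correlation), 4 luminal genes were higher, and the luminal list had an adjusted p of 5.86e-11, or an adjusted p of 0.0904 with an estimated correlation. The mesenchymal and matrix list had no called member and a camera adjusted p of 0.00386, which became 0.808 with an estimated correlation, 0.585 without HS 578T and 0.206 without BT-549. The epithelial list did not pass (camera adjusted p = 0.804) but was lower without T-47D (adjusted p = 0.0475) and higher without both MDA-MB-435 and MDA-N (adjusted p = 0.00103, and adjusted p = 0.75 with an estimated correlation). Its first member CDH1 ranged from 3.54 to 10.87 in the 7 lines. VIM ranged from 5.92 to 13.32.

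Of 143 genes called in the breast panel, 107 were higher and 36 lower. The cyclin gene CCNE2 was higher by 1.19 ± 0.19 (SE, adjusted p = 0.000753), with all 7 lines above the median of the other lines. MGP, an inhibitor of calcification, was higher by 2.22 ± 0.51 (SE), a call lost without T-47D, in which it was at 11.3 while the other 6 lines lay at 6.38 or below. The fatty acid binding protein FABP5 was 6.42-fold and the peroxidase PRDX1 4.66-fold lower, and both calls were lost without MDA-MB-435, without MDA-N, without both and with related lines averaged. FABP5 also lost it without T-47D and with the other lines pooled. The count was 77 without HS 578T, 78 without MDA-MB-435, 87 without T-47D, 50 without MDA-N, 309 without BT-549, 92 without both MDA-MB-435 and MDA-N, and 60 with related lines averaged.

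Many extracellular matrix and mesenchymal genes were higher in the central nervous system lines. Of 35 mesenchymal and matrix genes 20 were higher and none was lower (camera adjusted p = 2.7e-22, and adjusted p = 0.0525 with an estimated correlation). The count was 13 without SF-539 or SNB-75. SPARC, a matrix glycoprotein, averaged 11.08 ± 0.51 (SD, n = 6) against 6.56, a difference of 4.52 ± 0.84 (SE), or 22.9-fold (adjusted p = 0.000509). The collagen genes COL1A2, COL5A2, COL5A1 and COL6A3 were higher by 4.08 ± 0.58, 3.56 ± 0.71, 3.19 ± 0.50 and 3.11 ± 0.75 (SE), and the cross-linking enzyme LOXL1 by 3.40 ± 0.61. The gap junction gene GJA1, abundant in astrocytes, had the largest difference, 4.65 ± 0.75 (SE), or 25-fold (adjusted p = 6.09e-05). DKK3 was higher by 3.31 ± 0.41. VIM was at 12.68 ± 0.30 (SD, n = 6) against 10.94, a difference of 1.74 ± 0.73 (SE) that was not called (adjusted p = 0.107).

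Of 26 neural and glial genes 4 were higher and 2 lower in these lines, and the list did not pass (camera adjusted p = 0.125). The neurofilament gene NEFL was higher by 2.82 ± 0.88 (SE), the proteoglycan SPOCK1 by 2.27 ± 0.62 and the radial glia gene FABP7 by 1.97 ± 0.56. Each lost its call with the other lines pooled, and NEFL and FABP7 with related lines averaged. NEFL also lost it without SF-295, SF-539, SNB-19 or U251, SPOCK1 without SF-268, SF-295 or SNB-75, and FABP7 without SNB-19, SNB-75 or U251. The myelin gene MBP was 3.6-fold lower, a call lost without any 1 line but SNB-75, with the other lines pooled, with the mean of probe sets and with related lines averaged. The list passed without SF-268 (adjusted p = 0.0252) and without SF-539 (adjusted p = 0.0277), while 2 members were higher without SF-295 or SF-539 and 1 without SNB-19, SNB-75 or U251. The astrocyte gene GFAP differed by -0.17 ± 0.08 (SE, adjusted p = 0.141) through its brightest probe set, but was higher by 1.53 (adjusted p = 0.00274) through its most variable one and by 0.68 (adjusted p = 0.00897) in the mean of its probe sets.

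Some epithelial genes were lower in the central nervous system lines. Of 29 epithelial junction and keratin genes 10 were lower (camera adjusted p = 5.06e-08, and adjusted p = 0.574 with an estimated correlation). That count was 5 without U251 and 6 without any other 1 of the lines. KRT19 was 14.8-fold, KRT8 5.8-fold and EPCAM 6.24-fold lower. VAMP8 was 13.5-fold and FABP5 13-fold lower. All 3 of KRT19, KRT8 and EPCAM, and likewise SPARC, lost their calls with the other lines pooled. In all 1103 genes were called, 523 higher and 580 lower, and with arrays centred on their medians 543 were higher and 339 lower. The count was 534 without SF-268, 570 without SF-539, 684 without SNB-75, 467 without U251, 526 with related lines averaged and 411 with the other lines pooled.

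Epithelial genes were higher in the colon lines. Of 29 epithelial junction and keratin genes 22 were higher and none was lower (camera adjusted p = 1.26e-31, and adjusted p = 0.0173 with an estimated correlation). The adhesion molecule EPCAM averaged 10.33 ± 0.44 (SD, n = 7) against 5.48, a difference of 4.84 ± 0.64 (SE), or 28.7-fold (adjusted p = 4.39e-07), with all 7 lines above the median of the other lines. KRT19 was higher by 4.02 ± 0.91, the E-cadherin gene CDH1 by 3.97 ± 0.82, the vesicle GTPase RAB25 by 3.62 ± 0.58 and KRT8 by 3.21 ± 0.64 (SE). RAB25 was at 3.89 in SW-620 and between 8.04 and 9.42 in the other 6 lines. Of 24 intestinal genes 11 were higher (camera adjusted p = 1.59e-17, and adjusted p = 0.0142 with an estimated correlation), and 16 were when adjusted over the list alone. The intestinal list score was 1.97 in replicate 1 of the panel, 1.84 in HCC-2998, 1.52 in KM12 and 0.73 in HT29, and between -0.14 and 0.28 in HCT-116, HCT-15 and SW-620. The called members included the brush border protein VIL1, higher by 2.46 ± 0.21 (SE, adjusted p = 2.63e-12), the lectin LGALS4, higher by 3.13 ± 0.41, and TSPAN8, higher by 3.89 ± 0.53. TFF3 was higher by 1.49 ± 0.42, a call lost without replicate 1 of the panel, KM12 or SW-620. CDX1 differed by 0.16 ± 0.08 (SE, adjusted p = 0.27).

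Some mesenchymal genes were lower in the colon lines. Of 35 genes of that list 12 were lower (camera adjusted p = 3.16e-13, and adjusted p = 0.268 with an estimated correlation). The intermediate filament gene VIM averaged 7.17 ± 2.04 (SD, n = 7) against 11.63, or 22-fold lower (adjusted p = 7.59e-06). SPARC was 10.9-fold, FN1 8.73-fold and CCN1 6.72-fold lower. Outside that list BASP1 was 12.9-fold, the mitophagy gene BNIP3 10.8-fold and MSN 9.74-fold lower. The secreted proteins S100P, PRSS3 and KLK6 were higher by 3.82 ± 0.49, 3.18 ± 0.36 and 3.13 ± 0.33 (SE), and LYZ by 3.38 ± 0.56. In all 733 genes were called, 490 higher and 243 lower.

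Some genes of the kidney tubule, of the matrix and of focal adhesions were higher in the renal lines. Of 20 renal tubule genes 6 were higher and none was lower (camera adjusted p = 1.74e-09, and adjusted p = 0.00474 with an estimated correlation). The nephron transcription factor PAX8 averaged 9.82 ± 0.57 (SD, n = 8) against 8.61, a difference of 1.21 ± 0.14 (SE, adjusted p = 7.27e-08), with all 8 lines above the median of the other lines. PDZK1IP1 was higher by 3.25 ± 0.34 (SE, adjusted p = 3.25e-09), PDZK1 by 1.99 ± 0.31, and the brush border peptidase ANPEP by 1.21 ± 0.33, a call lost without replicate 1 or 5 of the panel or without CAKI-1. Outside the list the tubular injury marker HAVCR1 was higher by 3.18 ± 0.29 (SE, adjusted p = 2.74e-11). PAX2 differed by 0.15 ± 0.07 (SE) through its brightest probe set, and was called at 0.80 through its most variable one and at 0.48 in the mean of its probe sets.

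Of 35 mesenchymal and matrix genes 9 were higher in the renal lines and none was lower (camera adjusted p = 5.34e-08, and adjusted p = 0.54 with an estimated correlation). Among the genes higher in these lines, SPARC rose by 3.44 ± 0.74, NNMT, which methylates nicotinamide, by 3.29 ± 0.70, the kinase PLK2 by 3.16 ± 0.42, the cytokine IL32 by 3.11 ± 0.46, DKK3 by 3.10 ± 0.36 and the proteoglycan VCAN by 2.99 ± 0.72 (SE). SPARC lost its call with the other lines pooled. The phosphoprotein SPP1 was 14.1-fold higher, a call that 7 alternatives ended, among them leaving out A498, ACHN, CAKI-1, replicate 5, TK-10 or UO-31. SPP1, HAVCR1 and VCAN were at 4.27, 4.23 and 4.77 in SN12C, far below the other 7 renal lines. Of 23 focal adhesion genes 5 were higher (camera adjusted p = 4.54e-08, and adjusted p = 0.0453 with an estimated correlation). The latter became an adjusted p of 0.0557 without MDA-MB-435 and MDA-N, and 3 members were higher without any 1 renal line other than A498 and SN12C. No target of hypoxia-inducible factors was called among 23, while 3 passed when adjusted over the list alone. That list had a camera adjusted p of 0.01, which became 0.574 with an estimated correlation and 0.368 without replicate 5, and 2 members were called without SN12C. CA12, its first member measured, differed by 0.69 ± 0.65 (SE, adjusted p = 0.692). Neither list was higher in the renal lines alone. In the central nervous system lines 2 of the 23 hypoxia-inducible factor targets were higher (camera adjusted p = 0.00488, and adjusted p = 0.521 with an estimated correlation). Of the 23 focal adhesion genes 5 were higher there (camera adjusted p = 0.000169, and adjusted p = 0.274 with an estimated correlation), and 1 was without SNB-75. Genes lower in the renal panel were fewer, with MYB 2.36-fold and KLHDC2 2.17-fold lower. For MYB the other panels include leukemia, where it was high, so its difference reflects the leukemia lines at least in part. Over the panels other than leukemia MYB averaged below 5.90, the median of all values. In all 349 genes were called, 243 higher and 106 lower. The count was 211 without A498, 222 without ACHN and 212 with the other lines pooled.

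Few genes were called in the lung panel. Its lines still resembled each other more than lines of other panels, with a mean correlation of 0.722 against 0.666. Only 2 of 11963 genes were called with limma, both higher, while 1038 had an unadjusted p under 0.05. The calcium-binding protein CABYR was higher by 1.02 ± 0.20 (SE, adjusted p = 0.0361), with 8 of 9 lines above the median of the other lines. PTGS2, the inducible cyclooxygenase, averaged 4.68 ± 1.38 (SD, n = 9) and was higher by 1.18 ± 0.21 (SE, adjusted p = 0.0117). It is named after its values were seen, because it lies below the median of all values. No gene was called without A549/ATCC or NCI-H322M, while 15 were without NCI-H226, 9 without HOP-92, 5 without HOP-62 or NCI-H23 and 4 without NCI-H522. CABYR lost its call without A549/ATCC, NCI-H322M, NCI-H460 or NCI-H522, without MDA-MB-435 and MDA-N, and with related lines averaged.

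No gene of the lung epithelium list was called among 14 measured (camera adjusted p = 0.241), and NKX2-1, a transcription factor of lung epithelium, differed by -0.08 ± 0.07 (SE). No neuroendocrine gene was called among 14 (camera adjusted p = 0.522), where CHGA differed by 0.03 ± 0.09. The epithelial list did not pass (camera adjusted p = 0.0787), and CDH1 there ranged from 3.49 to 10.69. It passed without HOP-62 (adjusted p = 0.0394), HOP-92 (0.0166), NCI-H226 (0.0496), NCI-H23 (0.0365), NCI-H460 (0.0449) or NCI-H522 (0.0103). Of 25 targets of the oxidative stress factor NRF2 none was called, while 5 passed when adjusted over the list alone. The list passed camera with the preset (adjusted p = 6.58e-13), but had an adjusted p of 0.138 with an estimated correlation. Its score was 2.48 in A549/ATCC, 2.25 in NCI-H460 and 1.71 in NCI-H322M, and between -0.61 and 0.45 in the other 6 lines. The quinone reductase NQO1, its first member, differed by 0.73 ± 0.32 (SE, adjusted p = 0.485). Outside the lung panel the NRF2 score was 2.36 in HCC-2998, 1.39 in A498 and 1.30 in replicate 1 of the colon panel. Without NCI-H23 and OVCAR-8 the NRF2 list was higher in the colon lines, with 3 members called. Its camera adjusted p there was 0.0011, and 0.718 with an estimated correlation. With only HCC-2998 left out, it did not pass in colon (camera adjusted p = 0.125).

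Some genes of the Müllerian duct, the embryonic source of the female reproductive tract, were higher in the ovarian lines. Of 20 Müllerian genes 5 were higher and none was lower (camera adjusted p = 7.2e-11, and adjusted p = 0.0048 with an estimated correlation), and 9 were when adjusted over the list alone. SOX17 was higher by 2.18 ± 0.27 (SE, adjusted p = 7.77e-07), with all 6 lines above the median of the other lines. PAX8 was higher by 0.96 ± 0.16 (SE, adjusted p = 0.000566), EMX2 by 1.56 ± 0.33 and MEIS1 by 1.20 ± 0.22, each with 4 of 6 lines above that median, and the secreted protein WFDC2 by 1.02 ± 0.24. EMX2 and WFDC2 lost their calls without OVCAR-3 or OVCAR-4, MEIS1 without OVCAR-3, and PAX8 with the other lines pooled. Only 2 members were higher without OVCAR-3 and 3 without OVCAR-4, and 8 were without OVCAR-8. The list score was 1.25 in OVCAR-3 and 1.22 in OVCAR-4, and it was below 0 in OVCAR-5, at -0.17, and in the array labelled OVCAR-8, at -0.21. Without MDA-MB-435 and MDA-N, 5 Müllerian genes were higher in the ovarian and 5 in the colon lines, where the list did not pass (camera adjusted p = 0.0745). In that fit the renal tubule list, which also holds PAX8 and EMX2, was higher in the ovarian lines, as was the lung epithelium list. Each had a camera adjusted p of 0.000187, and an adjusted p of 0.116 with an estimated correlation.

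Of 29 epithelial genes 2 were higher in the ovarian lines, KRT7 by 3.50 ± 0.82 and the desmosomal gene DSP by 2.74 ± 0.63 (SE), with a camera adjusted p of 1.58e-08 and an adjusted p of 0.54 with an estimated correlation. Both lost their calls without OVCAR-3 or OVCAR-4 and with the other lines pooled. KRT7 also lost it without OVCAR-5 or SK-OV-3, and DSP without IGROV1, so that 1 member was higher without IGROV1, OVCAR-5 or SK-OV-3, and 5 were without OVCAR-8. The matrix gene MFAP5 was 7.79-fold higher (adjusted p = 0.000557), FGF18 4.23-fold (adjusted p = 7.05e-05) and SPON1 4.12-fold (adjusted p = 0.000505). CDH1 differed by 0.00 ± 0.88 (SE, adjusted p = 1), with values from 3.6 to 8.24. In all 43 genes were called, 41 higher and 2 lower. The count was 28 without IGROV1, 17 without OVCAR-3, 16 without OVCAR-4, 104 without OVCAR-8 and 21 with the filter on dim genes.

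The prostate panel holds only PC-3 and DU-145, so its values describe 2 lines. Of 17 called genes, all higher, several were high in 1 line alone. HOXB13, a homeobox gene of prostate, was at 8.81 in 1 line and 5.39 in the other, and its difference of 1.46 ± 0.34 (SE, adjusted p = 0.0481) was -0.25 without PC-3. PRSS3 ranged from 5.95 to 11.84. The channel gene VDAC2 was at 11.22 and 12.01 against 10.47, higher by 1.15 ± 0.24 (SE, adjusted p = 0.0253), and COMMD3 at 8.84 and 9.59 against 7.9 (adjusted p = 0.0176). VDAC2 lost its call without PC-3, with arrays centred on their medians and with the other lines pooled, and COMMD3 lost it without DU-145. HOXB13 was the 1 gene called among 12 measured of the prostate list, which did not pass (camera adjusted p = 0.217), though it did without DU-145 (adjusted p = 0.0277), and none was called without PC-3. The kallikrein KLK3 differed by 0.02 ± 0.15 (SE). The epithelial list did not pass either (camera adjusted p = 0.361). The count of called genes was 11 without PC-3 and 63 without DU-145, and 8 with arrays centred on their medians or with the filter on dim genes.

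The melanoma lines were marked by genes of the pigment cell. Of 24 measured melanocyte genes 23 were higher (camera adjusted p = 7.94e-59, and adjusted p = 7.33e-05 with an estimated correlation). The melanosome antigen MLANA averaged 11.12 ± 2.61 (SD, n = 8) against 5.12, a difference of 6.00 ± 0.52 (SE), or 64-fold (adjusted p = 3.09e-12). PMEL, which builds the fibrils of the melanosome, was higher by 4.18 ± 0.41, GPNMB by 4.88 ± 0.55 and MITF, the transcription factor of the lineage, by 2.84 ± 0.40 (SE). The survival gene BCL2A1 was 20.4-fold, QPCT 19.8-fold, SRPX 17.7-fold, the protease CAPN3 15.8-fold and SPARC 15.3-fold higher. The calcium-binding protein S100B was higher by 3.89 ± 0.51 (SE). LOX IMVI stood apart from the other 7 lines, with MLANA at 4.83 against 11.1 or more and a melanocyte list score of -0.09 against 1.67 or more.

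Cancer-testis antigens, normally silent outside the germ line, were higher for 5 of 11 genes in the melanoma lines (camera adjusted p = 4.54e-08, and adjusted p = 0.097 with an estimated correlation), and for 3 without UACC-257. MAGEA6 was higher by 3.73 ± 0.84, MAGEA12 by 3.41 ± 0.66 and PRAME by 3.29 ± 0.52 (SE). MAGEA6 and MAGEA12, whose probe sets may cross-hybridise, were at 4.74 and 4.36 in MALME-3M and at 8.76 or more in the other 7 lines. MAGEA1 was higher by 1.92 ± 0.58, a call lost without LOX IMVI, SK-MEL-2, UACC-257 or UACC-62. Of 26 neural and glial genes 4 were higher and 1 lower (camera adjusted p = 0.105, and adjusted p = 0.0427 without SK-MEL-28). FABP7 was higher by 2.29 ± 0.50 and the myelin enzyme CNP by 0.94 ± 0.16, and CLU was 3.92-fold lower, while GFAP differed by -0.11 ± 0.07 (SE). Of 29 epithelial genes 10 were lower (camera adjusted p = 2.54e-09, and adjusted p = 0.521 with an estimated correlation), with KRT19 14.8-fold and KRT8 9.75-fold lower. CD24 was 15.1-fold and the glutamine transporter SLC38A1 8.81-fold lower. In all 928 genes were called, 606 of them higher.

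**Figure D2:**
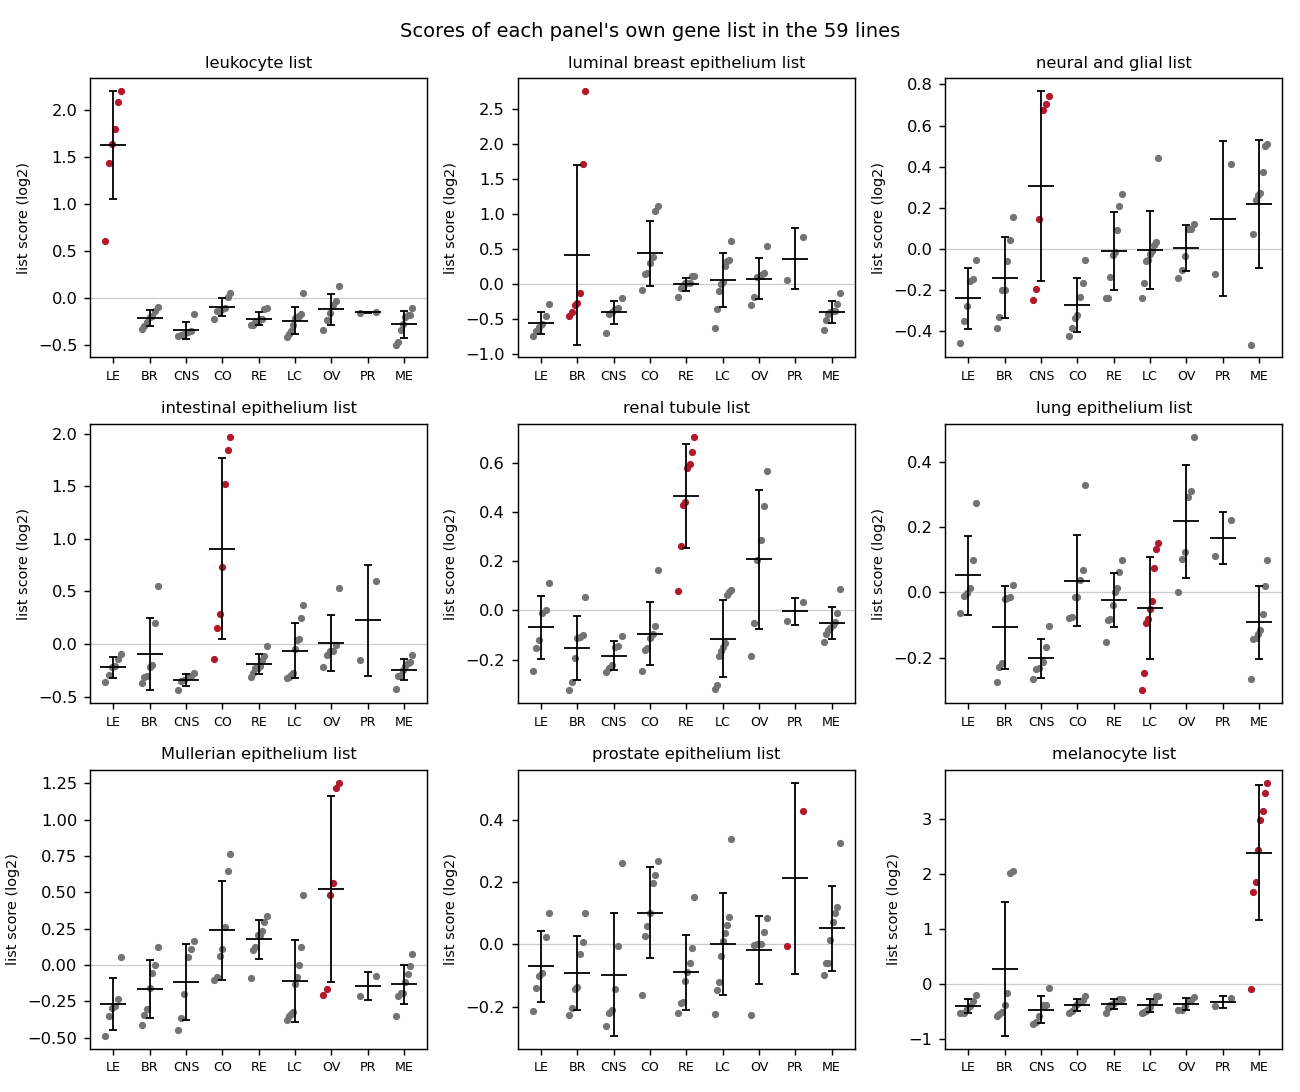
Score of each panel's own gene list (mean over the members of the log2 value minus the mean of the panel means) in the 59 lines, 1 dot per line, with red dots for the panel the list was fixed for and bars for the mean ± SD of each panel. The melanocyte list was at 2.02 and 2.06 in MDA-MB-435 and MDA-N of the breast panel and at -0.09 in LOX IMVI of the melanoma panel.

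Among 35 measured genes of drug transport and drug targets, 19 differed among the panels by the F test. The growth factor receptor gene EGFR differed most, at 9.88 ± 0.72 (SD, n = 8) in the renal lines and 4.27 ± 0.44 (SD, n = 6) in the leukemia lines, with adjusted p-values of 0.000256 and 1.41e-06 against the other panels. It was also lower in the melanoma lines, by a difference of -2.21 ± 0.48 (SE). NQO1, which activates quinone drugs, was at 7.87 ± 0.87 (SD, n = 6) in the leukemia lines, a difference of -2.83 ± 0.38 (SE, adjusted p = 1.28e-07). The efflux pump gene ABCC1 was at 7.43 ± 0.27 (SD, n = 8) in the melanoma lines, a difference of -0.61 ± 0.11 (SE, adjusted p = 0.00011), and was higher by 0.51 ± 0.13 (SE, adjusted p = 0.0487) in the ovarian lines. DPYD, which degrades fluorouracil, was higher by 2.41 ± 0.47 (SE) in the central nervous system lines, at 6.6 ± 0.68 (SD, n = 6). It differed by -1.55 ± 0.44 (SE) in the colon lines, at 3.08 ± 0.13 (SD, n = 7). The means of the remaining panels lay between 3.68 and 4.84, like colon below 5.90, where a gene can be unexpressed. TOP1, the target of camptothecins, was higher by 0.56 ± 0.14 in the leukemia lines and differed by -0.49 ± 0.13 in the renal lines. The tubulin gene TUBB2A differed by -1.89 ± 0.48 in the leukemia lines and was higher by 1.64 ± 0.48 (SE, adjusted p = 0.0254) in the central nervous system lines. ERBB2 differed by -1.29 ± 0.28 in the leukemia lines, and ABCC5 by 0.40 ± 0.11 in the melanoma lines. With the other lines pooled, the calls of EGFR and ABCC5 in melanoma, DPYD in colon, TOP1 in renal, TUBB2A in central nervous system and ABCC1 in ovarian lines were lost. Calls were also lost for TUBB2A in leukemia without HL-60(TB), for TUBB2A in central nervous system without SF-268, SNB-19 or U251 or with related lines averaged, for DPYD in colon without HCC-2998, for TOP1 in renal without A498 or through other choices of probe set, for ABCC5 without SK-MEL-28, UACC-257 or UACC-62, and for ABCC1 in ovarian lines under 11 further alternatives, among them leaving out OVCAR-3, OVCAR-4, OVCAR-5 or SK-OV-3. SK-OV-3 had ERBB2 at 11.23, while the other 5 ovarian lines lay between 7.68 and 8.42.

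Lines of a panel resembled each other more than lines of other panels. The nearest line was of the same panel for 43 of 59 lines, and the highest count among 100000 permutations was 21 (one-sided permutation p = 1e-05, the smallest they can give). All 6 leukemia and all 7 colon lines had their nearest line in their own panel, as did 7 of 8 renal, 6 of 8 melanoma and 6 of 9 lung lines. The same held for 4 of 7 breast, 4 of 6 central nervous system, 3 of 6 ovarian and 0 of 2 prostate lines. MDA-MB-435 and MDA-N were each other's nearest line, as were SNB-19 and U251. These pairs, catalogued as related, are part of the breast and central nervous system counts, and the permutations treat them as unrelated lines. The mean correlation within the renal panel was 0.819, against 0.671 with other lines, and within the breast panel 0.643, against 0.638. M14 had MDA-MB-435 as its nearest line (r = 0.897), and LOX IMVI had HOP-62 of the lung panel (r = 0.75). The highest correlation of all 1711 pairs, 0.996, was between the array labelled NCI-H23 of the lung panel and the array labelled OVCAR-8 of the ovarian panel. It exceeded that of MDA-MB-435 with MDA-N (r = 0.98) and of SNB-19 with U251 (r = 0.925). Without both arrays the ovarian count was 102, the lung count 3, and 8 of 20 Müllerian genes were higher in the ovarian lines.

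**Figure D3:**
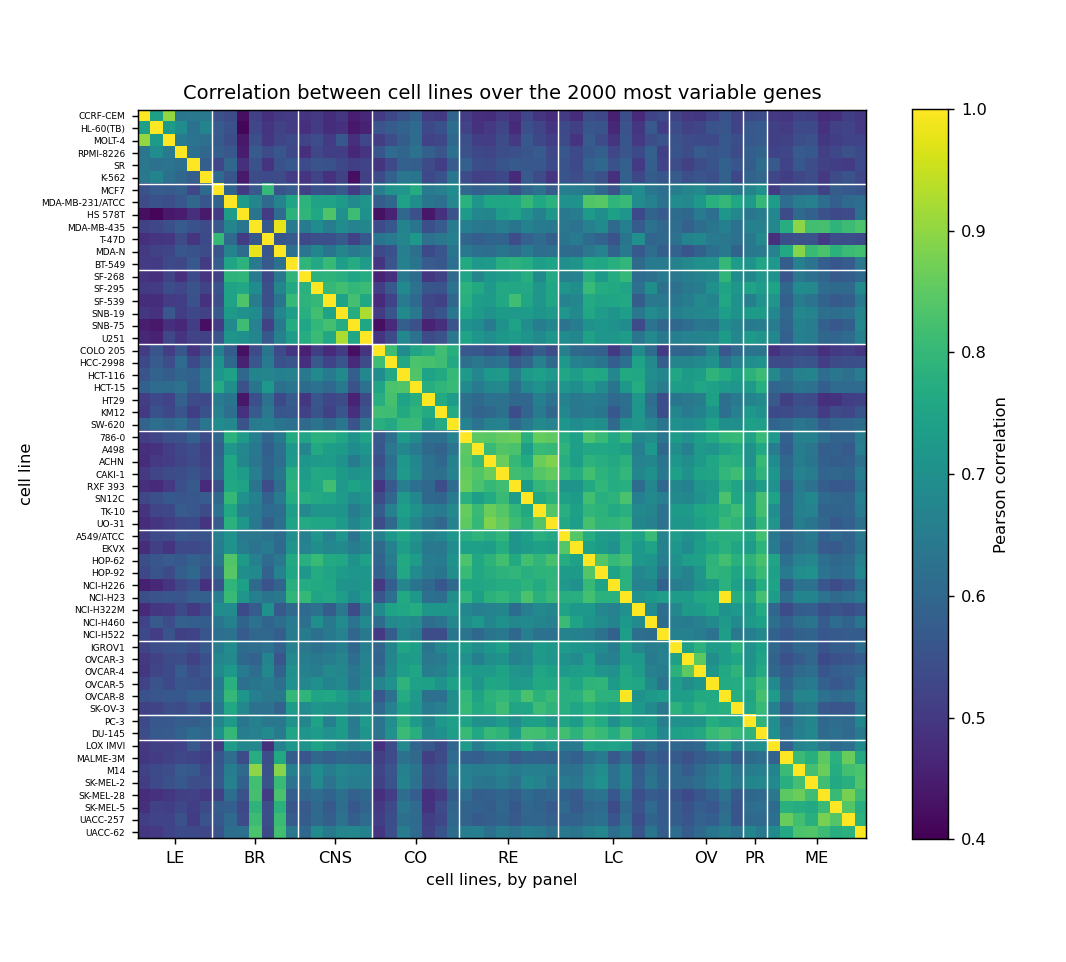
Pearson correlation over the 2000 most variable genes between the 59 cell lines, ordered by panel with white lines between panels, from 0.411 to 0.996 between different lines. The bright cell off the diagonal joins the arrays labelled NCI-H23 and OVCAR-8, and MDA-MB-435 and MDA-N of the breast panel form bright bands against the melanoma lines.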

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

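The tests of the authors' normalization and of OVCAR-8 RNA for the array pair, of a mixture with cells like another breast-coded line, and of RNA degradation in LOX IMVI were chosen after the result was seen, and so was the fit without NCI-H23 and OVCAR-8. Of 211 sets of values within a panel, 39 had a line standing far from the others by Dixon's ratio. Chance gives about 10.6 for independent, normally distributed sets. The sets here were the named genes, many picked for large differences, and list scores that share genes with them. No conclusion is therefore drawn from the excess over 10.6.

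The arrays labelled NCI-H23 and OVCAR-8 are nearly identical. The SD of the differences between them was 1.257 times as large over the fifth of genes that vary most among lines as over the fifth that vary least, while the ratio ran from 2.061 to 6.525 in the next 20 pairs, so the difference between these arrays looks like noise. That is consistent with RNA of 1 line on both arrays, a mislabelled sample, while the normalization drawing arrays together is argued against by the median correlation of all pairs, 0.641. The array labelled OVCAR-8 correlated with the other 8 lung lines and the other 5 ovarian lines at means that differed by 0.008, which does not say which label is wrong. NCI/ADR-RES, catalogued as derived from OVCAR-8, correlated with the less similar of both arrays by 0.079 more than with its next line, which is consistent with RNA of OVCAR-8 on both, a hypothesis from values already seen, and no biological explanation was tested.

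Melanocyte genes were high in MDA-MB-435 and MDA-N, coded as breast. The lower of their melanocyte list scores, 2.02, lay within the range of the melanoma lines and above the highest of the 49 other lines outside that panel, -0.07, which is consistent with lines of melanocyte type, against their panel code. MLANA was 10.39 and 10.6 there, and the lower value differed by -1.61 from the melanoma median of 12, which met the prediction, written beforehand, for cultures in which melanoma cells are a minority, but MITF was 9.36 and 9.48 against a median of 9.5 in the melanoma lines other than LOX IMVI, which does not go with it, so that explanation stays open. A mixture test was chosen only after that result, and its thresholds were changed after a first choice left too few genes to decide. With the changed thresholds, genes at 9 or more in another breast-coded line and under 6 in the melanoma lines other than LOX IMVI had medians of at most 4.98 in both lines, below the 7 needed for a large admixture of such a line.

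Some melanocyte genes were low in LOX IMVI. GPNMB was 4.61, MITF 5.25 and MLANA 4.83 there, below the 10.62, 8.21 and 11.1 that the other melanoma lines reached at least, while BCL2A1 of the same list was 8.23 against 4.41 in SK-MEL-2, and its neural and glial list score was -0.47. RNA degradation is argued against by its ACTB 3′ minus 5′ difference of -0.07, below the median of 0.38 in the other melanoma lines. RNA of another cell type could not be settled: of 312 other genes called 2-fold higher in the melanoma panel without it, LOX IMVI had 21.8% above the midpoint, between the median of 12.5% and the highest value of 26.9% in the 49 lines outside the panel other than MDA-MB-435 (65.1%) and MDA-N (69.6%). A mesenchymal state of the line is a candidate explanation that stays open, since its mesenchymal and matrix list score was 0.61 and no other melanoma line exceeded -0.01.

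In the leukemia panel HL-60(TB) stood high in AZU1 (9.86), ELANE (11.83), MPO (12.16) and the myeloid list score (3.3). K-562 stood high in HBZ (11.04), KLF1 (9.07), PTK2 (7.55) and the erythroid list score (2.8), and low in CORO1A (5.61) and HCLS1 (6.76). RPMI-8226 stood high in JCHAIN (10.3), POU2AF1 (9.39), PLS3 (8.14) and the B lymphoid and plasma cell list score (1.83). SR stood high in LAMC1 (8.02) and MYOF (8.1).

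In the breast panel SMARCE1 was 4.96 in BT-549, below the other lines, SEL1L3 was 7.74 in HS 578T, above them, TFAP2A was 6.6 in MDA-MB-231/ATCC, below them, and MGP was 11.3 in T-47D, above them. KRT8 was 8.79 in U251, above the other central nervous system lines. In the colon panel RAB25 was 3.89 in SW-620 and between 8.04 and 9.42 in the other lines. SPARC was 3.77 in KM12 and between 3.98 and 4.13 in the others, all below 5.90, where a gene can be unexpressed. The epithelial list score of 2.4 in NCI-H322M lay above that of the other lung lines.

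In the melanoma panel CLU was 7.38 in MALME-3M, above the other lines, while MAGEA12 (4.36) and MAGEA6 (4.74) in MALME-3M and BCL2A1 (4.41) in SK-MEL-2 lay below them. In the ovarian panel KRT7 was 4.26 in IGROV1, below the other lines, and ERBB2 was 11.23 in SK-OV-3, above them. In the renal panel HAVCR1 (4.23), SPP1 (4.27) and VCAN (4.77) in SN12C and NNMT (8.18) in TK-10 lay below the other lines, and the list score of hypoxia-inducible factor targets was 1.46 in replicate 5, above them.

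The counts were set beside 99 other random assignments of the panel codes to the lines, 100 splits with the real one. The real count was matched by 1 split, itself, in leukemia (1943 genes, highest other 219), breast (143 against 15), central nervous system (1103 against 95), colon (733 against 50), renal (349 against 113) and melanoma (928 against 29), and for the F test (3708 against 72). With 100 splits no share can be lower. All codes were shuffled at once, so real differences between panels widened the spread within random ones and could lower their counts. The splits also scatter MDA-MB-435 and MDA-N, and SNB-19 and U251. With these related lines averaged, the breast and central nervous system counts were 60 and 526. The splits therefore do not exclude chance for a single panel. In the ovarian panel 3 of 100 splits gave as many as its 43, with a highest other of 100. Chance is also not excluded for the lung panel, where 8 splits gave 2 genes or more, up to 8. The same holds for the prostate panel, where 54 splits gave 17 or more, up to 424. The reason for so high a number was not tested.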

How the results depend on the processing

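The 3′ to 5′ covariate and the fit without NCI-H23 and OVCAR-8 were chosen after the data were seen. The counts for leukemia, colon, melanoma and the F test stayed within 1.5 times under each alternative run, as did the nearest-line count, and the own lists of these panels and of the renal and ovarian panels stayed past the threshold. The luminal breast list lost its call with an estimated correlation (adjusted p = 0.521). Against 2 in the main setting, the lung count was 5 with median centring, 5 with the filter on dim genes, 7 with the mean of probe sets, 6 with the most variable probe set, 1 without MDA-MB-435 and MDA-N and 1 with related lines averaged. Other counts that moved were prostate, 17, to 8 with median centring and 8 with the filter, ovarian, 43, to 21 with the filter, where fewer genes were tested, and to 102 without NCI-H23 and OVCAR-8, central nervous system, 1103, to 411 with the other lines pooled and 526 with related lines averaged, renal, 349, to 212 with the other lines pooled, and breast, 143, to 92 without MDA-MB-435 and MDA-N and 60 with related lines averaged. Leaving out 1 line gave 50 to 309 genes in breast, 467 to 920 in central nervous system, 211 to 368 in renal, 0 to 15 in lung, 16 to 104 in ovarian and 11 to 63 in prostate. With 1 prostate line left, that line is assumed to vary like the lines of the other panels.

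Of 196 named results 118 stayed on their side of the threshold throughout, and of their 3414 values under all settings 286 lost the call, 5 gained it and 8 reversed. GFAP in the central nervous system reversed to 0.681 with the mean of probe sets and 1.532 with the most variable one. Over the fits without 1 line, JCHAIN in leukemia ran from -0.072 without RPMI-8226 to 1.37, and MPO in LE from -0.02 without HL-60(TB) to 1.485. For the prostate panel, PRSS3 in PR ran from -0.21 to 5.678, HOXB13 in PR from -0.25 to 3.172 and TFF2 in PR from -0.158 to 2.781, each lowest without PC-3, and LMO3 in PR from -0.033 without DU-145 to 3.404. For GFAP the cause was not tested, and for the others the line left out is the one that carried the gene. No paired analysis was possible because every array is labelled as a different cell line and replicate numbers only name lines. The alternative offsets were not run because the table is already on a log scale. Values near the floor limit what dim genes can show, and another probe set of such a gene can give another sign, as for GFAP.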

Other observations

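The named genes of the first 3 paragraphs were chosen after their values were seen, as were the list tests that leave out 1 line. Genes of MHC class II presentation, which normally mark antigen-presenting cells, were higher in the melanoma lines for 4 of 9 genes (camera adjusted p = 0.00514, and adjusted p = 0.579 with an estimated correlation). HLA-DRA was at 7.41 ± 2.63 (SD, n = 8), a difference of 1.58 ± 0.49 (SE, adjusted p = 0.0353), HLA-DPA1 differed by 1.48 ± 0.35 and HLA-DPB1 by 1.33 ± 0.32, with probe sets that may cross-hybridise. By the F test none of the 9 genes differed among the panels. The list score was 2.50 in M14 and 2.46 in SK-MEL-2, between 0.74 and 0.88 in UACC-62 and SK-MEL-28, and below 0 in the other 4 lines. Outside the panel it was 1.30 in MDA-N, 1.27 in SR, 1.15 in RPMI-8226 and 1.14 in HOP-92. Without M14 the list did not pass (adjusted p = 0.0642) and 1 member was higher, and without SK-MEL-2 it did not pass either (adjusted p = 0.055), with 2 higher, as without UACC-62.

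Of 30 proliferation genes 6 were higher and 2 lower in the leukemia lines, and the list did not pass (camera adjusted p = 0.319). The higher ones included the replication helicase genes MCM6, by 1.02 ± 0.21 (SE, adjusted p = 0.000304), MCM5, by 0.92 ± 0.23, and MCM2, by 0.71 ± 0.16. The clamp gene PCNA was higher by 0.70 ± 0.19. The mitotic ubiquitin-conjugating enzyme gene UBE2C differed by -1.50 ± 0.26 (SE, adjusted p = 2.97e-05). In the melanoma lines 3 of the 30 were lower, among them MCM2 by a difference of -0.88 ± 0.14 (SE, adjusted p = 1.57e-05), and the list was lower (camera adjusted p = 0.00108, and adjusted p = 0.677 with an estimated correlation). In the central nervous system lines 3 were higher and none lower (camera adjusted p = 0.000844, and adjusted p = 0.657 with an estimated correlation), with none higher without SF-268, SNB-19 or U251 and 1 without SNB-75. In the prostate lines the proliferation list was lower with no member called (camera adjusted p = 0.00837, and adjusted p = 0.771 with an estimated correlation), which did not hold without PC-3 (adjusted p = 0.489). In leukemia 1 was lower without HL-60(TB) or MOLT-4. The melanoma count was 1 without SK-MEL-2, UACC-257 or UACC-62 and 5 without M14.

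No gene of MHC class I presentation was called among 11 in the renal lines (1 without replicate 5, and 1 without MDA-MB-435 and MDA-N), where 3 passed when adjusted over the list alone and the list had a camera adjusted p of 0.000677, or an adjusted p of 0.579 with an estimated correlation. With no member called, it was lower in the ovarian lines (camera adjusted p = 0.0081, and adjusted p = 0.726 with an estimated correlation), but not without IGROV1 (adjusted p = 0.132). It was also lower in the prostate lines (camera adjusted p = 0.0497, and adjusted p = 0.813 with an estimated correlation), but not without PC-3 (adjusted p = 1) or without NCI-H23 and OVCAR-8 (adjusted p = 0.0614). The endothelial list did not pass in any panel, with camera adjusted p-values from 0.183 in colon to 0.893 in melanoma. Of 22 interferon response genes 2 were higher in the leukemia lines, where IFITM1 was higher by 2.81 ± 0.69 (SE), and the list did not pass there (camera adjusted p = 0.409). In the ovarian lines it was lower with no member called (camera adjusted p = 0.0403, and adjusted p = 0.871 with an estimated correlation), but not without IGROV1 (adjusted p = 0.0777), OVCAR-3 (0.0885), OVCAR-8 (0.0962) or SK-OV-3 (0.0796), nor without NCI-H23 and OVCAR-8 (0.0915). The list of drug transport and drug targets did not pass in any panel, and its lowest camera adjusted p was 0.105, in lung.

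NCI/ADR-RES, the line in no panel, correlated most with the arrays labelled NCI-H23 (r = 0.901) and OVCAR-8 (r = 0.901), and next with SN12C (r = 0.821). The drug efflux pump gene ABCB1 was at 9.84 in NCI/ADR-RES, above all 59 other lines, of which HCT-15 was highest at 8.09 and the array labelled OVCAR-8 was at 3.98. MSLN was 8.08 in NCI/ADR-RES and 5.07 in the array labelled OVCAR-8, B2M 4.69 and 9.98, and UBB 4.79 and 11.98. Each of these is a single array with no replicate, and the genes were chosen after their values were seen.

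Control probe sets differed between panels. The mean 18S ribosomal RNA signal was 6.39 ± 0.28 (SD, n = 7) in the breast lines and 7.54 ± 0.85 (SD, n = 8) in the renal lines. The mean ACTB 3′ minus 5′ difference ran from 0.05 ± 0.38 (SD, n = 7) in breast to 0.42 ± 0.33 (SD, n = 6) in ovarian lines. The spike-in control BioB averaged 12.7 ± 0.32 (SD, n = 8) in the renal lines and 12.1 ± 0.37 (SD, n = 6) in the central nervous system lines. With a covariate for the 3′ to 5′ difference the breast count was 121 and the ovarian count 41.

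A hypothesis fixed before its test was that epithelial and mesenchymal list scores run opposite to each other among lines of the same panel. The lists share 0 genes. With each panel's mean removed, Pearson's r over 59 lines was -0.53 (permutation p = 0.014) and Spearman's rho -0.32 (permutation p = 0.025), and r was -0.4 without the 2 lines farthest from the median. Within single panels, 8 of which had at least 6 lines, the relation passed in colon alone, where r was -0.98 over 7 lines (exact permutation p = 0.0002, adjusted p = 0.0016) and rho was -1.0 (exact permutation p = 0.0004), with r at -0.89 without the 2 farthest lines. HCT-116 and SW-620 had the lowest epithelial scores there, 1.17 and 1.02, and the highest mesenchymal ones. In the other 7 panels r ran from -0.65 to 0.14, with adjusted exact permutation p-values of 0.37 or more. Without the 2 farthest lines r moved to -0.9 in leukemia, from 0.14, to -0.78 in ovarian, from -0.43, and to 0.11 in breast lines, from -0.65, and it was between -0.26 and 0.12 in the other 4 panels. Whether the relation differs between panels was not tested.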
